A study of Mus musculus with 4 samples.

How the data were processed

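The series holds 4 mouse RNA-seq libraries: 1 of spleen NK cells, 1 of bone marrow ILC2 and 2 of the MNK-3 line. Per the labels' protocols, NK cells and ILC2 came from pooled C57BL/6 mice of 8 to 12 weeks, and MNK-3 from day 15 fetal thymocytes of NIH-Swiss mice. Cytokines for ILC2 and MNK-3 were used at 10 ng/ml, and no concentration is given for NK. Total RNA was purified with an RNeasy Plus Micro kit and had integrity numbers above 9, libraries were made with a SMARTer Stranded Total RNA-seq v2 Pico kit, and pairs of 38 bp reads came from an Illumina sequencer. The protocols also call for 2 technical replicates per experiment, whereas each deposited table has 1 column of values, so whether runs were pooled is not known.

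Per the submitters' processing notes, reads were aligned with STAR 2.7.8a and counted per gene with HTSeq on mm10/GRCm38. The strand setting and the gene set were not stated. The deposited values are in a unit recorded as other: they are whole-number HTSeq read counts per gene, not normalized, in tables that are tab-separated under another type of name. NK and ILC2 were counted over 53465 Ensembl genes and MNK-3 over 31053. Only the 30731 genes in all tables were used, which left out 22734 genes listed for NK and ILC2 alone and 322 listed for MNK-3 alone. The genes left out held 3.05% of gene reads in NK, 1.89% in ILC2, and 0.131% and 0.0399% in the MNK-3 libraries. Symbols came from the reference for 30615 of the shared genes, and coordinates from GENCODE M21 for 30692. All 13 mitochondrially encoded genes had no counts in NK and ILC2, so no fold is given for them; mt-Co1 had 849 and 2052 CPM in MNK-3. The entries that name no gene (no feature, ambiguous or unaligned) held 49.3% of reads in NK, 25.9% in ILC2, 76.5% in MNK-3 replicate 1 and 26.6% in MNK-3 replicate 2, and were left out.

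The samples, comparisons, gene lists, named genes, size rules and most alternatives were fixed before the data were examined. The test fixed then was a quasi-likelihood fit in edgeR, which was not run, because the tables could not be read as counts by the check on their unit, although their values are whole numbers. The test used instead was limma voom (limma 3.58.1, R 4.3.3), with all 4 libraries in 1 fit of 3 groups, which leaves 1 residual degree of freedom from the MNK-3 pair, moderated across genes. The prior degrees of freedom were estimated as infinite, so each SE and p-value rests on the spread pooled over genes and gives no weight to a gene's own spread. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Genes were kept by a filter with a minimum count of 10 scaled to library size and a minimum total of 15, written to the published definition, which left 25283 genes. Library scaling used own code for trimmed means of M values (TMM, trimming 30% of ratios and 5% of abundances), with factors of 1.04 for NK, 0.816 for ILC2, 1.39 for MNK-3 replicate 1 and 0.852 for MNK-3 replicate 2. The pair of MNK-3 libraries differed by more than counting error (chi-square over degrees of freedom 69.7, Pearson r 0.925 and Spearman rho 0.896 across genes, which are not independent replicates), so they were kept as 2 libraries.

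Tested on simulated data, with 200 of 22048 genes changed and a squared coefficient of variation of 0.05, the fit recovered 14.9% of genes changed 2-fold, 82.1% of those changed 4-fold and 93.9% of those changed 8-fold, and called 52 of 21848 unchanged genes. The median dispersion between the MNK-3 libraries at over 100 CPM was 0.222, above the simulated value, so these recoveries do not carry over to the data. In the main scaling, genes at 100 CPM or more in replicate 2 had a median log2 ratio of -0.97 for replicate 1 over replicate 2 (interquartile range -1.09 to -0.827). An offset shared by most genes can enter the dispersion, so 0.222 need not be gene-by-gene spread alone.

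For sizes, a log2 ratio of TMM-scaled CPM was taken after adding 0.5 CPM, with the mean of both libraries for MNK-3. A gene counted by size at 4-fold or more with at least 10 CPM in the higher group, and a gene was set apart in a cell type at 8 times both other groups with at least 10 CPM. Each of 30 gene lists was summarised by the median log2 ratio of its measured members and by the number at 2-fold or more, called, and called when adjusted over the list alone. Where members had no counts in a group, the median was also taken with those at their floor, over the members above the floor in either group and with no CPM added, so it differs from the main median also in that. The gene lists cover group 1, group 2 and group 3 identity, the cytotoxic granule, the natural killer gene complex, chemokines, secreted cytokines, proliferation, histones, glycolysis, cholesterol synthesis, interferon-stimulated and immediate early genes, MHC class I and class II, and markers of T cells, B cells and myeloid cells, among others.

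Folds against a library with no counts are lower bounds from a floor of 3 counts per library, which is 0.624 CPM in NK, 0.395 in ILC2, 0.0845 in MNK-3 replicate 1 and 0.232 in MNK-3 replicate 2. Intervals for ratios of 2 libraries are exact 95% binomial intervals and, like the floors, cover counting error only, since reads without molecular identifiers are not independent molecules. Named genes were 15 identity genes in every comparison, the 2 highest and 2 lowest members of each list, the 5 called genes (or, for NK against ILC2, the 5 genes) with the largest ratio in each direction at 50 CPM or more, and the 5 most abundant genes set apart in each cell type. Ribosomal, immunoglobulin, predicted and unnamed genes were left out of the last 2 parts.

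Alternatives were median-of-ratios factors, library totals, leaving out mitochondrial and structural RNA genes, thinning to the smallest library, no filter on low counts, a fit of only the libraries compared, an added 2-fold threshold, an assumed coefficient of variation of 0.4 in an own negative binomial likelihood ratio test, looser and stricter size rules, and leaving out each MNK-3 library. TMM factors from genes of at least 50 CPM, and the direction of the called genes and the set-apart genes without MNK-3 replicate 1, were added after the data were seen. Summaries used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1, and plots used matplotlib 3.10.9.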

Results

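RNA was sequenced from 3 kinds of mouse innate lymphoid cell, lymphocytes that carry no rearranged antigen receptor, to profile expression in cells that were also taken for Hi-C, a map of contacts within the genome. Natural killer (NK) cells stood for group 1 and came from the spleen of C57BL/6 mice, with 1 library. Group 2 cells (ILC2) came from C57BL/6 bone marrow and had been expanded in IL-2, IL-7, IL-33 and IL-25, with 1 library. Group 3 was represented by MNK-3, a cell line with ILC3-like features derived from fetal thymocytes of NIH-Swiss mice and kept in IL-7 and IL-15, with 2 libraries. Reads in the genes shared by all libraries came to 4637812 in NK, 9298162 in ILC2, 25617762 in MNK-3 replicate 1 and 15177345 in MNK-3 replicate 2. Cell type coincided with tissue and culture, and in MNK-3 also with strain and with the gene set used for counting, so no comparison separates these.

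MNK-3 replicate 1 stood apart from the other 3 libraries. It had 75.8% of its reads outside genes, against 47.1% in NK, 23.1% in ILC2 and 24.3% in MNK-3 replicate 2, and it held at least 1 count in 95.6% of shared genes, against 69.6% to 76.0% in the others. Genes under 1 CPM (read count scaled to library size) in replicate 2 had a median log2 ratio of 2.00 in replicate 1 over replicate 2 (11958 genes), whereas genes at 100 CPM or more had a median of -0.97 (3373 genes). Both values depend on the scaling. The main factors were 1.39 and 0.852 for replicates 1 and 2, against 1.02 and 1.16 from abundant genes, chosen after the data were seen. With the latter, or with library totals, replicate 1 lies higher relative to replicate 2. The gap between the MNK-3 values of abundant genes given below is then smaller, and that at low levels larger. A low MNK-3 level seen in replicate 1 alone is therefore given with its replicate 2 value throughout. The p-values measure only the spread between these libraries, which may be technical, and the lone NK or ILC2 library is assumed to vary as the MNK-3 pair did.

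**Figure D1:**
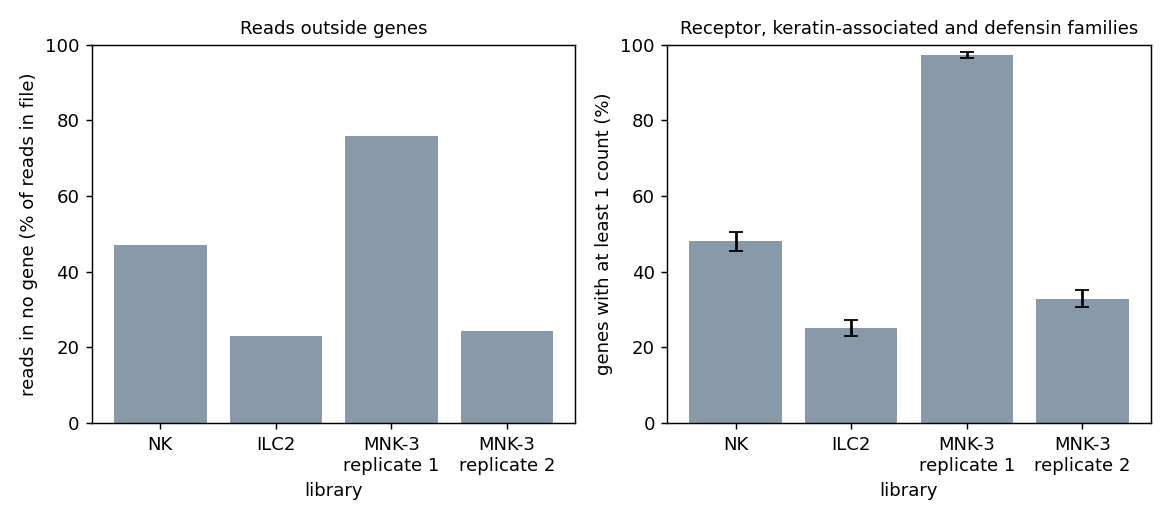
Left, the percent of each library's reads that fell in no gene. Right, the percent of 1602 genes of receptor, keratin-associated and defensin families with at least 1 count, with 95% Wilson intervals as error bars. MNK-3 replicate 1 is the highest library in both panels, at 75.8% and 97.4%.

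The first comparison asks how the group 3 line differs from group 1 cells. The group 1 programme was lower in MNK-3 than in NK cells, though not all of it was absent. All 22 measured members of the group 1 and NK identity list lay at least 2-fold lower in MNK-3, with a median log2 ratio of -5.82. Ncr1, which encodes the activating receptor NKp46, had 1076 CPM in NK against 2.45 and 5.80 CPM in the 2 MNK-3 libraries. Tbx21 and Eomes, the T-box regulators of NK cells, had 449 and 874 CPM in NK, against 21.1 and 21.4 CPM for Tbx21 and 19.9 and 35.0 CPM for Eomes in MNK-3. MNK-3 in turn held Il23r, the receptor for IL-23 in group 3 cells, at 151 and 359 CPM against no counts in NK. Cell cycle transcripts were higher in the line, with 29 of 30 proliferation genes at least 2-fold higher.

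Ncr1 (ENSMUSG00000062524, chromosome 7, 4337724 to 4345164, mm10) was lower in MNK-3 by a log2 fold of -8.47 (SE 1.26, limma voom, adjusted p 4.07e-07). Tbx21 (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331) had a log2 fold of -4.40 (SE 0.99, limma voom, adjusted p 0.00355), and Eomes (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132) had -5.00 (SE 1.09, limma voom, adjusted p 0.00199). Of the group 1 list, 15 of 22 members passed the test, all lower in MNK-3, and 20 passed when adjusted over the list alone. Without MNK-3 replicate 1 the list median was -7.49. Against ILC2 the same list was mixed, with 9 members at least 2-fold higher in MNK-3 and 2 lower, or 6 and 5 without MNK-3 replicate 1. Ifng, the main group 1 cytokine, had 51.2 CPM in NK and 1.72 CPM and 0 in MNK-3, and did not pass (limma voom, adjusted p 0.531). Il2rb, the IL-2 and IL-15 receptor chain, and the Fc receptor gene Fcgr3 were the least different members, at 1763 and 68.1 CPM in NK against 248 and 547 CPM and 20.2 and 44.8 CPM in MNK-3.

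The natural killer gene complex on chromosome 6, which encodes lectin-like receptors, was lower in MNK-3 at 21 of 26 genes, with a median log2 ratio of -5.34, and -6.59 without MNK-3 replicate 2. In this list 9 genes passed the test, all lower, and 19 passed when adjusted over the list alone. Klrk1, which encodes NKG2D, had 910 CPM in NK against 2.25 and 0.155 CPM in MNK-3 (log2 fold -9.77, limma voom, adjusted p 0.00254). The Ly49 genes Klra4 and Klra8 had 530 and 343 CPM in NK and at most 0.197 CPM in MNK-3. They belong to a paralogous family that differs between mouse strains, and the NIH-Swiss line was mapped to the C57BL/6 reference. Cd69, an activation marker within the same complex, had 43.5 CPM in NK against 60.9 and 146 CPM in MNK-3.

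Cytotoxic granule genes were split. The pore-forming protein gene Prf1 had 1443 CPM in NK against 3.77 and 0.387 CPM in MNK-3 (log2 fold -9.39, SE 1.75, limma voom, adjusted p 0.000115), and the granzyme gene Gzma had 2208 CPM against 5.04 and 0.0774 CPM (log2 fold -10.42, SE 2.14, limma voom, adjusted p 0.000712). Gzmb was also lower, with 553 CPM in NK and 6.87 and 13.6 CPM in MNK-3 (log2 fold -5.98, limma voom, adjusted p 2.48e-05). Gzmc went the other way, at 14.8 and 35.7 CPM in MNK-3 and 0.624 CPM in NK, and did not pass. Over the 15 listed genes 8 were at least 2-fold lower and 3 higher, 7 passed the test, all lower, and 7 passed when adjusted over the list alone. The median was -1.15, against -3.76 without MNK-3 replicate 1, -2.04 without replicate 2 and -4.79 after thinning.

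Group 3 genes were higher in MNK-3, at 17 of 21 members, with a median log2 ratio of 3.57, or 4.17 with 0-count members at their floor, and 2.88 without MNK-3 replicate 2. Of these, 1 passed the test as higher, Rora, a regulator of group 2 and group 3 cells (ENSMUSG00000032238, chromosome 9, 68653786 to 69388246), with 933 and 2162 CPM against 35.0 CPM in NK (log2 fold 5.44, SE 1.24, limma voom, adjusted p 0.00424). When adjusted over the list alone, 6 passed as higher and 2 as lower. The 2 lower members were Ncr1 and Il18r1, a chain of the IL-18 receptor that had 573 CPM in NK against 4.20 and 2.94 CPM in MNK-3. Il23r was at least 576-fold higher in replicate 2 than the floor in NK. Kit, the stem cell factor receptor, had 753 and 1802 CPM against 71.0 CPM (log2 fold 4.14, limma voom, adjusted p 0.0543). It was called with library totals, after thinning, with no filter on low counts and with only the 3 libraries compared. Ahr, the aryl hydrocarbon receptor, had 128 and 304 CPM against 18.5 CPM. The effector cytokines of group 3 had low counts: Il22 had 5.58 and 10.3 CPM, and Il17a had 0.817 and 0.387 CPM. The deposited counts hold 0 reads marked as aligned to more than 1 place. Whether reads of Il22 were lost because they also match Iltifb, a gene listed with it among the locus neighbours, was not tested. This bears on every Il22 value given below.

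Among group 2 genes the comparison was mixed. Gata3, the group 2 regulator, had 122 CPM in NK and 70.3 and 109 CPM in MNK-3, and the group 2 list median of 1.10 turned to -0.37 without MNK-3 replicate 1. In that list 1 gene passed as higher, Rora, and 1 as lower, Klrg1, with the same counts when adjusted over the list alone. Il5, Il13 and Il1rl1 had no counts in MNK-3 replicate 2.

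Proliferation genes had a median log2 ratio of 4.14. Cenpf, a kinetochore protein gene, was the 1 member that passed, with 511 and 966 CPM against 18.1 CPM in NK (log2 fold 5.35, SE 1.39, limma voom, adjusted p 0.0283), and 16 passed when adjusted over the list alone. Replication-dependent histone genes were higher at 19 of 21 members with a median of 3.11, none passed the test by limma voom and 4 passed when adjusted over the list alone. Cholesterol synthesis genes had a median of 1.68, with 12 of 19 higher and none lower, and glycolysis genes a median of 0.92, with 7 of 17 higher and none lower. Without MNK-3 replicate 2 the medians were 3.21 for proliferation, 1.91 for histones, 1.18 for cholesterol synthesis and 0.24 for glycolysis. No cholesterol synthesis or glycolysis gene passed the test by limma voom, also when adjusted over the list alone.

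Of 24 immediate early genes, which are induced by activation or by cell handling, 15 were at least 2-fold lower and 6 higher in MNK-3, 4 passed as lower, and when adjusted over the list alone 8 passed as lower and 2 as higher. Klf2, a regulator of lymphocyte trafficking, had 546 CPM in NK against 7.83 and 7.89 CPM in MNK-3, and Dusp2, a phosphatase gene, 338 CPM against 16.8 and 0.464 CPM. Nr4a1, an orphan nuclear receptor gene induced by signalling, had 292 and 703 CPM in MNK-3 and 48.7 CPM in NK. Chemokine and chemokine receptor genes were lower at 13 of 26 and higher at 9, with 5 passing as lower, and when adjusted over the list alone 12 as lower and 1 as higher. Without MNK-3 replicate 1, 17 were lower and 4 higher, and the median went from -0.59 to -1.88. Ccl5 had 1780.0 CPM in NK and 3.86 and 2.32 CPM in MNK-3, and the receptor gene Cxcr6 had 5.41 CPM in NK and 240.4 and 561 CPM in MNK-3. MHC class I genes were lower at 8 of 14 with a median of -1.33, none passed by limma voom and 5 passed when adjusted over the list alone. Whether strain differences affect the mapping of reads to these genes or to the Ly49 genes was not tested. Without MNK-3 replicate 2 the immediate early median went from -1.45 to -2.14 and the class I median to -2.43.

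Medians for markers of other cell types depended on replicate 1. The T cell list had a median log2 ratio of 1.39 over NK, and -1.03 without MNK-3 replicate 1. B cell markers went from 1.06 to -0.66 and myeloid markers from 0.64 to -0.97 in the same step. In the T cell list 1 member, the receptor signalling chain Cd247, passed as lower in MNK-3, also when adjusted over the list alone. It had 256 CPM in NK, where it signals for Fc receptors and NKp46.

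Over all 25283 genes tested, limma voom called 133 at a Benjamini-Hochberg adjusted p under 0.05, 2 higher in MNK-3 (Cenpf and Rora) and 131 lower. This split depended on the setting: it was 73 higher and 517 lower with library totals, 255 and 317 after thinning, and 2690 and 787 with an assumed coefficient of variation of 0.4. By limma voom 882 genes had an unadjusted p under 0.05, a smaller share than the 0.05 that no difference at all would give. Over genes at large the test thus gave few small p-values, and a gene that did not pass is not shown to be unchanged. This does not make the calls safe. In the simulated data 52 unchanged genes were called, beside the 10, 55 and 62 genes recovered of those changed 2-fold, 4-fold and 8-fold. With the spread pooled over genes, a gene with a wide spread of its own can pass. By size, 2116 genes differed at least 4-fold, 1554 higher and 562 lower in MNK-3. Without MNK-3 replicate 1 these were 1330 and 801, of which 1231 and 535 were the same genes, without replicate 2 they were 1424 and 885, and with median-of-ratios factors 1182 and 757. The median log2 ratio of all genes was 0.69, against 0.38 with median-of-ratios factors, 0.88 with library totals and 0.02 without MNK-3 replicate 1. All 133 called genes kept their direction at 2-fold or more against replicate 2 alone, but this outcome was close to fixed in advance. Replicate 2 is part of the data that chose these genes, and all 133 were at 2-fold or more in the fit. The calls themselves depended on the scaling: with factors from abundant genes, chosen after the data were seen, 58 genes were called, of which 2 were among the 133, and none of the called genes named above was among the 58. Of these, Rora, Cenpf, Tbx21 and Eomes also lost the call with median-of-ratios factors, and Cenpf, Klrk1, Klra4, Klra8 and Klrg1 with library totals.

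**Figure D2:**
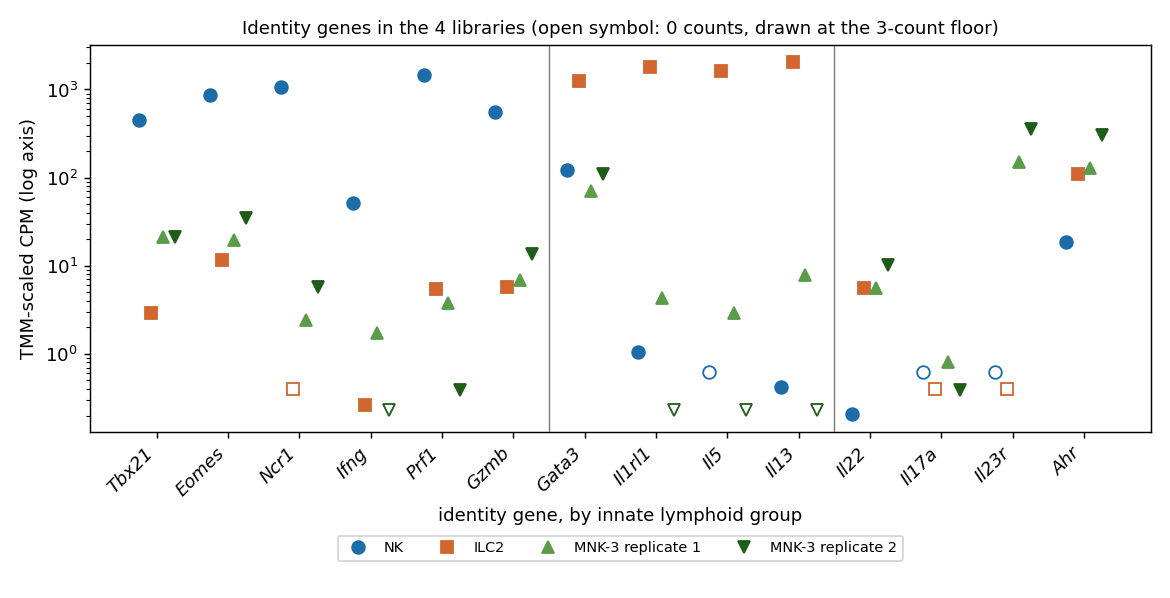
TMM-scaled CPM on a log axis for 14 identity genes of the 3 innate lymphoid groups, with 1 point per library and open symbols for 0 counts, drawn at the 3-count floor. Tbx21, Eomes, Ncr1, Ifng, Prf1 and Gzmb were highest in NK, Gata3, Il1rl1, Il5 and Il13 in ILC2, and Il23r in both MNK-3 libraries.

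The next comparison sets the group 3 line against expanded ILC2. The type 2 effector genes were abundant in ILC2 and had no counts in MNK-3 replicate 2: Il5, the eosinophil growth factor, had 1635 CPM in ILC2, Il13 had 2038 CPM, and Il1rl1, which encodes the IL-33 receptor, had 1784 CPM. Il23r was again the reverse, with no counts in ILC2. Glycolysis genes were lower in MNK-3 at 16 of 17 members and cholesterol synthesis genes at 16 of 19. Proliferation genes differed little by the mean of both MNK-3 libraries, with 0 of 30 at 2-fold or more. Their median was 0.69 without MNK-3 replicate 1, with 4 of 30 higher, and -0.71 without replicate 2.

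Il5 (ENSMUSG00000036117, chromosome 11, 53720794 to 53725106) had a log2 fold of -11.48 (limma voom, adjusted p 0.0120), and its neighbour Il13 (ENSMUSG00000020383, chromosome 11, 53631324 to 53634702) had -10.58 (SE 2.41, limma voom, adjusted p 0.00712). Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415) had -11.16 (SE 2.59, limma voom, adjusted p 0.0102). In MNK-3 replicate 1 these genes had 2.93, 7.86 and 4.28 CPM. In replicate 2, against the 3-count floor of that library, they were at least 7044-fold, 8780-fold and 7688-fold lower than in ILC2. Over the group 2 list, 19 of 23 genes were at least 2-fold lower and 3 higher, with a median log2 ratio of -3.78. In this list 8 genes passed the test, all lower, and 16 passed when adjusted over the list alone. Gata3 (ENSMUSG00000015619, chromosome 2, 9857078 to 9890034) had 1244 CPM in ILC2 against 70.3 and 109 CPM in MNK-3, a log2 fold of -3.77 that did not pass (limma voom, adjusted p 0.296) but was called with library totals, with factors from abundant genes and after thinning. Il2ra, the high-affinity IL-2 receptor chain, had 2764 CPM against 150.3 and 298 CPM and did not pass either. Rora, by contrast, had 609 CPM in ILC2 and 933 and 2162 CPM in MNK-3.

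Other genes set the ILC2 apart as well. Peg10, an imprinted gene of retrotransposon origin, had 3122 CPM in ILC2 against 3.38 and 0.232 CPM in MNK-3 (log2 fold -10.87, SE 2.09, limma voom, adjusted p 0.000675). Tph1, the first enzyme of serotonin synthesis, had 1731 CPM against 5.83 and 0.232 CPM, and Pla2g7, a secreted phospholipase gene, 1102 CPM against 2.03 and 0.0774 CPM. Secreted cytokine genes had a median log2 ratio of -0.40, or -0.72 with 0-count members at their floor, with 12 of 25 lower and 7 higher. There 7 passed as lower, and when adjusted over the list alone 9 passed as lower and 1 as higher. This median was 0.02 with library totals, but -1.26 and -1.16 without MNK-3 replicate 1 or 2 and -1.44 after thinning.

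Group 3 genes were higher in MNK-3 at 15 of 21 members, with a median of 3.08, against 3.43 without MNK-3 replicate 1 and 1.95 without replicate 2. None passed as higher by limma voom, 1 passed as lower, and when adjusted over the list alone 4 passed as higher and 3 as lower. The gene that passed, Batf, encodes a basic leucine zipper factor and had 198 CPM in ILC2 against 8.84 and 10.1 CPM in MNK-3. Il23r (ENSMUSG00000049093, chromosome 6, 67422932 to 67491855) was at least 909-fold higher in replicate 2. Il22 had 5.67 CPM in ILC2 and 5.58 and 10.3 CPM in MNK-3, a log2 fold of 0.23 that turned to -0.03 with median-of-ratios factors and -0.41 without MNK-3 replicate 2, and was 0.77 without replicate 1.

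Glycolysis genes had a median log2 ratio of -1.99, and -2.92 without MNK-3 replicate 2. Slc16a3, a lactate exporter gene, passed as lower, with 445 CPM in ILC2 against 19.5 and 1.55 CPM in MNK-3, and 3 passed when adjusted over the list alone. Aldoa, an aldolase gene, had 3265 CPM against 211 and 461 CPM. Cholesterol synthesis genes had a median of -1.66, none passed by limma voom and 4 passed when adjusted over the list alone. The proliferation median was 0.34, against 0.69 without MNK-3 replicate 1 and -0.71 without replicate 2. For histone genes it was -0.28, against 0.14 without MNK-3 replicate 1, -1.41 without replicate 2 and 0.03 with library totals. No gene of either list passed, also when adjusted over the list alone.

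Interferon-stimulated genes were higher in MNK-3 at 13 of 19 and lower at 2, with a median of 2.10, or 1.29 without MNK-3 replicate 1. None passed by limma voom, also when adjusted over the list alone. The immediate early list had 11 of 24 genes higher and 3 lower with a median of 0.91, and none passed by limma voom. When adjusted over the list alone, 3 passed as higher and 1 as lower. In it Nr4a3 had 369 and 887 CPM in MNK-3 against 2.77 CPM in ILC2. MHC class II genes had a median of -1.09 and -2.09 without MNK-3 replicate 1, with none called by limma voom. Here 1 passed as higher and 1 as lower when adjusted over the list alone, and Cd74, the invariant chain, had 105 and 242 CPM in MNK-3 against 17.9 CPM. Markers of other cell types again followed replicate 1: the T cell median was 2.28 (3.26 with 0-count members at their floor) and 0.00 without it, the B cell median 1.49 (2.00 at the floor) and -0.28, and the myeloid median 1.16 (1.71) and -0.12.

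Of 25283 genes, limma voom called 86 at a Benjamini-Hochberg adjusted p under 0.05, 2 higher and 84 lower in MNK-3, with 906 at an unadjusted p under 0.05. The share of 906 is again below the 0.05 that no difference would give, so genes that did not pass are not shown to be unchanged. The split was 228 higher and 603 lower with library totals, 60 and 210 after thinning, and 6925 and 1125 with an assumed coefficient of variation of 0.4, where most calls were higher. The 2 higher were Ptprf, a receptor tyrosine phosphatase gene at 241 and 535 CPM against 12.0 CPM (SE of the log2 fold 1.31, limma voom, adjusted p 0.0414), and Rnf43, a ubiquitin ligase gene that restrains Wnt signalling, at 239 and 527 CPM against 21.3 CPM (log2 fold 4.15, SE 1.09, limma voom, adjusted p 0.0442). Rnf43 was chosen after its values were seen. By size, 1621 genes differed at least 4-fold, 953 higher and 668 lower in MNK-3. That balance turned with the libraries and the scaling: it was 687 and 808 without MNK-3 replicate 1, where 589 and 591 were the same genes, and 1229 and 1244 without replicate 2. With median-of-ratios factors it was 639 and 935, with library totals 1602 and 437, and with factors from abundant genes 1366 and 527. The median log2 ratio of all genes was 0.78, against 0.54, 1.13 and 1.04 in these 3 scalings, and 0.01 without MNK-3 replicate 1.

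All 86 called genes kept their direction at 2-fold or more against replicate 2 alone, which was likewise close to fixed in advance. Replicate 2 is part of the data that chose these genes, and all 86 were at 2-fold or more in the fit. With factors from abundant genes 157 genes were called, of which 1 was among the 86. None of the called genes named for this comparison was called there, while Gata3, Il2ra and Aldoa were. Batf, Ptprf and Rnf43 also lost the call with median-of-ratios factors, and Il5, Il1rl1, Pla2g7 and Ptprf with library totals.

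**Figure D3:**
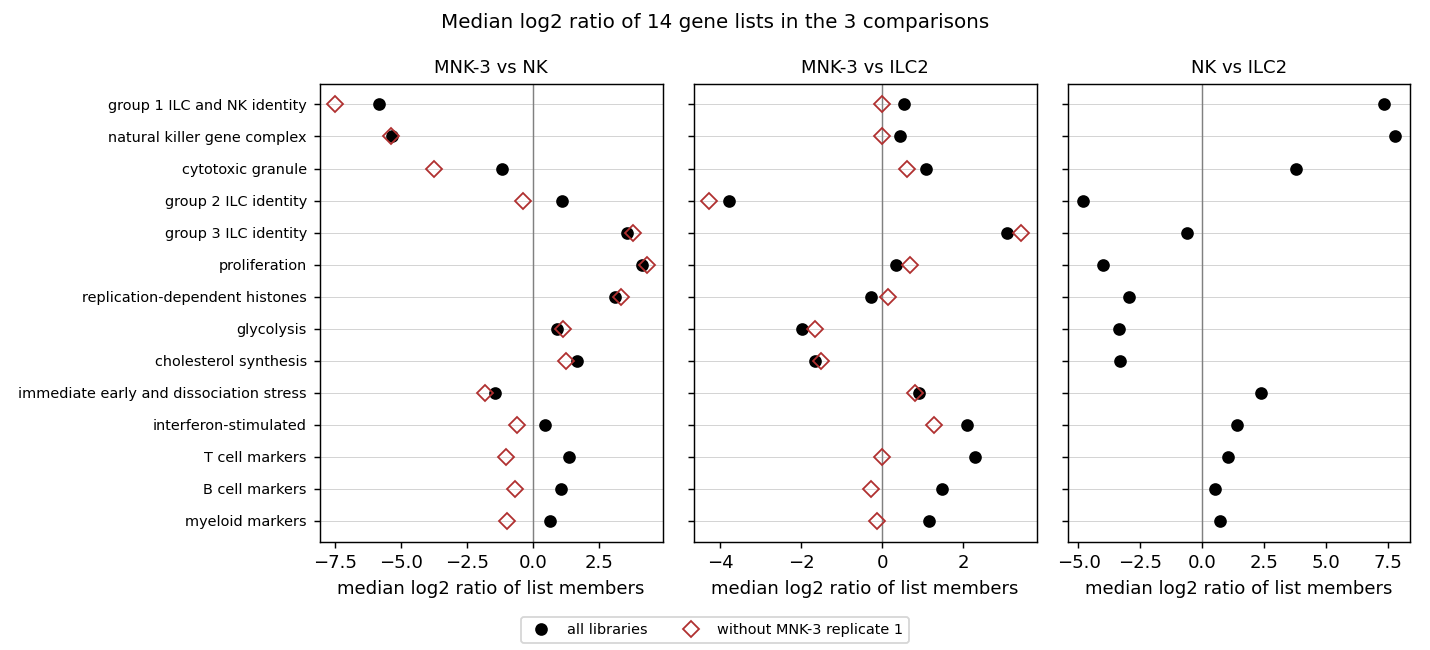
Median log2 ratio of the members of 14 gene lists in the 3 comparisons, for all libraries (filled points) and without MNK-3 replicate 1 (open diamonds). The group 1 list is at -5.82 for MNK-3 against NK and at 7.36 for NK against ILC2, and the T cell list moves from 1.39 to -1.03 without replicate 1.

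The last comparison sets NK against ILC2, with 1 library each, so no p-value is given and no replicate check exists. Intervals are exact 95% counting intervals, which cover counting error only. Each library held its own programme: 21 of 22 group 1 genes and 23 of 26 genes of the natural killer gene complex were at least 2-fold higher in NK, and 19 of 23 group 2 genes were at least 2-fold lower. Ncr1 was at least 2721-fold higher in NK than the floor in ILC2, and Il5 at least 2618-fold higher in ILC2 than the floor in NK. At least 2-fold lower in NK were 16 of 17 glycolysis genes, all 19 cholesterol synthesis genes and 28 of 30 proliferation genes.

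In the group 1 list the median log2 ratio was 7.36, or 8.04 with 0-count members at their floor, and in the natural killer gene complex 7.80. Tbx21 was 155-fold higher in NK (interval 102 to 248) and Eomes 74.5-fold (60.4 to 93.0). Klrk1 was at least 2302-fold higher and Klri2, another lectin-like receptor gene, at least 1647-fold. Klrb1c, which encodes NK1.1, had 1 count in ILC2, and its ratio of 5236 had an interval of 939 to 206853. Zeb2, a regulator of late NK maturation that is on the list, did not differ in this way, at 590.1 CPM in NK and 599 CPM in ILC2. Cytotoxic granule genes had a median of 3.80 over 15 genes, with 9 higher and 1 lower, and 5.28 after thinning. Over the 11 genes above the floor in either library, with 0-count members at their floor, it was 4.96. There Gzma was 798-fold higher (522 to 1289), Prf1 267-fold (197 to 373) and Gzmb 95.3-fold (70.8 to 132).

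In the group 2 list the median was -4.81. Il13 had 2 counts in NK, and the ILC2 ratio of 4895 had an interval of 1355 to 40422. Il1rl1 was 1715-fold higher in ILC2 (735 to 5281), Il2ra 604-fold (399 to 963) and Gata3 10.2-fold (9.36 to 11.1). Tph1 and Pla2g7 were 1663-fold (712 to 5122) and 1324-fold (517 to 4859) higher. Secreted cytokines had a median of -2.39 over 25 genes and -3.30 after thinning. Over the 22 genes above the floor in either library, with 0-count members at their floor, it was -4.10. The group 3 list had 4 genes higher and 9 lower in NK and a median of -0.61 over 21 genes. Over the 16 genes above the floor in either library, with 0-count members at their floor, it was -2.04, with Il17a and Il23r at or under the floor in both libraries. Ahr was 5.92-fold higher in ILC2 (4.76 to 7.46), and Il22 had 1 count in NK and an ILC2 ratio of 27.2 (4.63 to 1099.8).

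The expanded ILC2 also had more of the transcripts of growth. Glycolysis, cholesterol synthesis, proliferation and histone lists had medians of -3.34, -3.32, -4.00 and -2.94 for NK over ILC2. Hk2, a hexokinase gene, was 133-fold higher in ILC2 (93.9 to 197), Sqle, a cholesterol pathway gene, 92.9-fold (48.8 to 204), and Plk1, a mitotic kinase gene, 48.7-fold (29.9 to 85.5). NK cells had more of the immediate early list, with 18 of 24 genes higher, 1 lower and a median of 2.37, and of the interferon-stimulated list, with 11 of 19 higher, 1 lower and a median of 1.41. Klf2 was 115-fold higher in NK (82.9 to 165) and Dusp2 65.8-fold (47.9 to 92.9). Chemokine genes had a median of 1.23, and Ccl5 was 356-fold higher in NK (259 to 503). T cell, B cell and myeloid marker medians were 1.03, 0.50 and 0.73. Over the 13, 9 and 10 genes above the floor in either library, with 0-count members at their floor, they were 3.07, -0.28 and 1.76, so the B cell markers have no clear direction. NK had 47.1% of its reads outside genes against 23.1% in ILC2, and its CPM per kilobase in the receptor, keratin-associated and defensin families was 3.44 times that of MNK-3 replicate 2, against 0.893 times in ILC2.

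By size 1801 genes differed at least 4-fold, 534 higher and 1267 lower in NK. With library totals these were 689 and 958, and with factors from abundant genes 722 and 957. The median log2 ratio of all genes was 0.05, against 0.26 and 0.29 in these 2 scalings.

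Genes that only 1 cell type held at 8 times the level of both others numbered 143 in NK, 179 in ILC2 and 234 in MNK-3. Without MNK-3 replicate 1 they numbered 203, 214 and 215, of which 143, 167 and 188 were the same genes. Among the most abundant in NK were Ahnak, a giant scaffold protein gene at 10541 CPM, and Gzma, Ccl5 and Prf1. The most abundant in ILC2 were Furin, a proprotein convertase gene at 4186 CPM, the lipid desaturase gene Scd2 at 3972 CPM, and Aldoa, Ero1l and Peg10. In MNK-3 they were Kit, Nr4a1, Ptprf, Fam84b and Ccnb1ip1, the last with 223 and 527 CPM against 1 count in NK and none in ILC2.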

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

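All tests in this part except that of active neighbours were chosen after the result was seen. MNK-3 replicate 1 had 75.8% of its reads outside genes, 82546115 reads that enter no comparison, which is above the level in the other libraries. The same library held counts in 97.4% of 1602 genes of olfactory, vomeronasal and taste receptor, keratin-associated and defensin families, against 48.0% in NK, 25.2% in ILC2 and 32.9% in MNK-3 replicate 2. Per kilobase of exon its CPM in these families was 33.7 times that of replicate 2, against 3.44 times in NK and 0.893 times in ILC2.

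Greater depth alone is argued against: after thinning to the gene reads of replicate 2, 97.2% of these genes still had a count. RNA from other cells may contribute, since a list of 5 T cell genes (Cd3d, Cd3e, Cd3g, Cd4 and Cd8a) had a median of 8.70 times the level of the receptor families, while the other 8 tissue lists reached at most 4.82 times and erythroid genes 0.387 times. The multiple depends on the reference: all 10904 protein-coding genes low in replicate 2 had a median of 27.8 counts per kilobase, above the 15.5 of the receptor families. Against these the T cell genes (134.9) stood under 5 times higher. The bound of 5 times was set for the receptor families, where it was met, and none was set for the low genes. In the fixed T cell list, 11 members as low in replicate 2 had a median of 111.9, at percentile 100 of random draws from the low genes. B cell markers lay at percentile 95.2, and erythroid and platelet markers at 5.82. The line itself derives from thymocytes, so the T cell counts need not come from other cells, and T cell RNA does not by itself account for counts in receptor families. Reads of genomic DNA stay open. Silent genes, here protein-coding genes with at most 2 counts in each other library, had on chromosome X 0.378 of the autosomal level (338 and 3803 genes). The interval of 0.296 to 0.454 comes from resampling genes, which are not independent replicates, and is not a counting interval. The ratio is inside the range of 0.3 to 0.7 set, after the value was seen, for DNA of a line with a single X. It is below the 0.9 set for the absence of DNA. The interval lies below the middle of that range and reaches just under it, so the ratio cannot decide. A lower level of stray RNA from chromosome X was not tested. Reads spread evenly over genomic DNA would not by themselves give the link with active neighbours described next. No biological explanation of the counts was tested.

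The level of these counts was uneven between genes. Counts per kilobase were higher where neighbouring genes were active, with a Spearman rho of 0.316 across 3565 genes after the trend with GC content was removed (0.418 before, and 0.359 for GC content itself). The 25% of genes with the least active neighbours had 8.70 counts per kilobase and the 25% with the most active 28.4. Genes are not independent replicates. GC content alone is argued against as the source of this link, since it stayed at 0.316. Unspliced or read-through RNA from active regions is a candidate source, which was not tested apart from other sources near active genes.

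The ILC2 library had Xist at 122 CPM beside Y-linked transcripts. Cells pooled from mice of both sexes may account for this, since all 4 Y-linked genes were above the floor and below NK, with a median ratio of 0.659. Other sources of both transcripts were not tested.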

How the results depend on the processing

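The factors from abundant genes, and the direction of called genes and the set-apart genes without MNK-3 replicate 1, were chosen after the data were seen. Genes called for MNK-3 against NK (133) and against ILC2 (86) were 590 and 831 with library totals, 58 and 157 with factors from abundant genes, and 101 and 55 with median-of-ratios factors. They were 572 and 270 after thinning and 3477 and 8050 with an assumed coefficient of variation of 0.4. The share of calls that were higher in MNK-3 went from 2 of 133 and 2 of 86 to 12.4% and 27.4% with library totals, 44.6% and 22.2% after thinning and 77.4% and 86.0% with the assumed variation. Of the 133 and 86, 99 and 59 were among those called with library totals, 2 and 1 with factors from abundant genes, 77 and 44 with median-of-ratios factors, and 127 and 73 after thinning. All 133 and 86 kept their sign in these 4 settings, which use the same libraries and so are no independent check. Genes at 4-fold or more were 3277 at a 1 CPM minimum and 972 at 8-fold for MNK-3 against NK (2116), 3825 and 768 against ILC2 (1621), and 879 at 8-fold for NK against ILC2 (1801). Leaving out 1 MNK-3 library gave 1495 to 2473 against ILC2. Of 29 list medians, mitochondrial genes aside, 9 against NK and 6 against ILC2 changed sign without MNK-3 replicate 1, and 4 and 5 without replicate 2. With library totals 1 and 5 changed sign, with factors from abundant genes 2 and 2, with median-of-ratios factors 3 and 2, and after thinning 1 and 1. For NK against ILC2 these were 3 with library totals, 3 with factors from abundant genes, 0 with median-of-ratios factors and 2 after thinning. Among the lists whose main median lay outside the central 95% of matched random lists, leaving out 1 MNK-3 library gave -0.37 to 1.34 (group 2), -0.48 to 0.83 (architecture), -0.34 to 1.91 (type 2 cytokine locus), -1.03 to 1.10 (T cell) and -0.84 to 0.63 (mast cell and basophil) against NK. Against ILC2 it gave -0.66 to 0.75 (architecture) and -0.71 to 0.69 (proliferation), and the T cell median, 0.00 to 2.62, reached 0 without changing sign. Of the same lists, secreted cytokines (0.024) and chemokines (0.11) against ILC2 changed sign with library totals, as did mast cell and basophil markers against NK (-0.14) with median-of-ratios factors. The log2 fold of Il22 against ILC2 (0.23) became -0.034 with those factors, and ranged from -0.41 to 0.77 when 1 MNK-3 library was left out. Without MNK-3 replicate 2 the median of all genes over 10 CPM went from 0.48 to -0.11 against NK and from 0.06 to -0.56 against ILC2. The architecture and proliferation medians fell along with it, so their turns are in part shared with genes at large and not particular to these lists. Beyond this the cause of the changes was not tested. No paired analysis was possible because no labels pair the libraries. A Wald test in DESeq2 was not run, for the reason given for edgeR, which was not run either, and separate columns of the NK and ILC2 tables were not compared because each has 1 column. Leaving out an MNK-3 library leaves no residual degrees of freedom, so it gives no count of called genes. Depth limits the NK library most, where 3 counts are 0.624 CPM.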

Other observations

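The factors from abundant genes were chosen after the data were seen, and values are given without explanation. Genes of genome architecture, the proteins that shape the contacts Hi-C maps, were compared as well. The list of CTCF, cohesin and condensin genes had a median log2 ratio of 0.57 for MNK-3 over NK, with 10 of 25 genes at least 2-fold higher and none lower, but -0.48 without MNK-3 replicate 2. All genes over 10 CPM had a median of 0.48 over NK, and random lists matched on expression 0.15. Over ILC2 the architecture median was 0.35, against 0.06 and -0.22 for these references, and -0.66 without replicate 2. For NK over ILC2 it was -0.31, against 0.07 with factors from abundant genes and 0.03 with library totals. No member was called by limma voom in either MNK-3 comparison, and 2 passed against NK when adjusted over the list alone. Ctcf itself, chosen after its values were seen, had 198 CPM in NK, 188 CPM in ILC2 and 146 and 316 CPM in MNK-3.

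Genes of the type 2 cytokine locus, Il5 and Il13 included, had a median of 1.80 for MNK-3 over NK, -0.34 without MNK-3 replicate 1, and none was called by limma voom, also when adjusted over the list alone. Over ILC2 their median was -0.16, against 0.23 with library totals, and -0.71 and -0.91 without MNK-3 replicate 1 or 2, with 2 called lower, Il5 and Il13 themselves, also when adjusted over the list alone. Ifng, Il22 and their neighbours had medians of 1.02 over NK and 0.64 over ILC2, which were 0.11 and -0.08 without MNK-3 replicate 2, with none called by limma voom, also when adjusted over the list alone. Il1rl1 and its neighbours had 0.32 over NK, -1.56 without MNK-3 replicate 1, with 1 called lower, Il18r1, and 2 when adjusted over the list alone. Over ILC2 they had 0.36, and -1.06 without replicate 1, with 2 called lower, Il1rl1 itself and Il1r2, a decoy receptor gene for IL-1, and 4 lower and 1 higher when adjusted over the list alone. Gata3 and its neighbours had 0.60 over NK, and -0.28 without MNK-3 replicate 2. All genes over 10 CPM had 0.48 over NK, and matched random lists 0.38. In the Gata3 list 1 was called lower, Prkcq, a kinase gene of antigen receptor signalling, also when adjusted over the list alone. Over ILC2 Gata3 and its neighbours had -0.54, and -1.44 without MNK-3 replicate 2, with none called by limma voom and 3 lower when adjusted over the list alone.

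Genes that part ILC1 from NK cells were higher in MNK-3 than in NK at 7 of 9, with a median of 2.63 and 1.63 without MNK-3 replicate 2, none called by limma voom and 3 when adjusted over the list alone. They were also lower in NK than in ILC2 at 8 of 9 and higher at 1, with a median of -3.94. For MNK-3 over ILC2 the median was 0.17, with 3 higher and 3 lower, and -0.14 and -0.47 without MNK-3 replicate 1 or 2. The difference from NK was thus shared with ILC2 and not particular to MNK-3. Tmem176a, a membrane protein gene, had 109.9 and 247 CPM against 0.624 CPM in NK. Precursor and pan-ILC regulators had a median of -0.56 over NK and -1.56 without MNK-3 replicate 2, with 1 called lower, Bach2, also when adjusted over the list alone, and -0.01 over ILC2, which was 0.31 with library totals, 0.36 without MNK-3 replicate 1 and -0.64 without replicate 2. Cytokine receptors had -0.22 over NK and -0.98 without MNK-3 replicate 2, with 3 called lower, and when adjusted over the list alone 5 lower and 1 higher. Erythroid and platelet markers had 0.61 over NK, and -0.54 without MNK-3 replicate 1, and mast cell and basophil markers 0.16 and -0.84. Matched random lists had 0.65 and 0.82 over NK. Sex-linked genes had 0.07 over NK, and -0.63 without MNK-3 replicate 2.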
